A study of Mus musculus with 3 samples.

How the data were processed

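Total RNA of CD86-positive dendritic cells was extracted with TRIzol, and 0.5 µg was amplified into Cy3-labelled cRNA for Agilent one-colour arrays, per the labels' protocols. The 3 groups have 1 array each, named LLC, LLC/SeV/GFP and LLC/SeV/GM from the treatment in the labels, and all 3 arrays lie on 1 slide. How many mice or nodes went into an array is not given in the sources used here. Each array holds 44397 spots, of which 43020 are not controls and stand for 39429 probes.

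Spot intensities were read with Agilent Feature Extraction 9.5.1.1, per the file headers. The processed signal is an intensity from which background was subtracted and a spatial and multiplicative trend removed, with surrogate values for spots not above background and no scaling between arrays, per the file headers. Probe coordinates use the mouse build mm9, per the file headers. The mean signal, the local background, the pixel SD and the flags for background, saturation and outliers come from the same deposited scanner files.

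The authors' deposited table of the series holds linear intensity values, 1 per probe. Its 3 columns share the same sorted values, with a median of 48.0 each, and rank the probes as the processed signals of the same arrays do (Spearman's rho of 1.00 for each array). It is therefore quantile normalized between arrays on a linear scale with higher values for brighter probes, and its method is not given in the sources used here. It served as an alternative. No column was left unmapped.

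Outlier spots were removed (137, 187 and 152 in the order above), which left out 2 probes and kept 39427. The log2 processed signals of the spots of a probe were averaged, and the 75th percentile of the array over probes that are not controls was subtracted. That percentile was a signal of 469 on the LLC array, 413 on the LLC/SeV/GFP array and 495 on the LLC/SeV/GM array. Names follow the scanner files, updated through RefSeq accessions where these matched (26053 probes). Of 31895 gene names 6285 have several probes, and the probe with the highest mean over the arrays stands for the gene. Other probes above background are given beside it where they clearly disagree. Values of probes above background on no array are mostly not given, also where they disagree, such as those of Flg, Ighg, Apol7a and Tfcp2l1. Probes of near-identical families (haemoglobins, Ifna, Klra, immunoglobulins) can share signal and were read as uncertain. No exon or UTR annotation of mm9 was used here, so only probe positions are given.

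A gene was called higher or lower when it differed by at least 1 log2 unit, was well above background on every array of the brighter side, and was not saturated. A probe counted as above background on an array when any of its kept spots did. With 1 array per group there is no test, and the rule of size describes these arrays. For a gene not well above background on the dimmer side, only a bound was taken, as the brighter value over the higher of the dim probe's own signal and the lowest signal well above background of that array (4.86, 3.41 and 3.31). Scaling matters because it moves all genes. The median difference of all genes was 0.00 in the main setting between LLC/SeV/GM and LLC/SeV/GFP and -0.01 between LLC/SeV/GFP and LLC. It was 0.18 and -0.23 with median centring and 0.23 and -0.37 with spike-in scaling, which also gave -0.14 between LLC/SeV/GM and LLC. Of the 10 spike-in probes 8 were above background on all arrays. After the main scaling, 1 of these differed by 1.17 between LLC/SeV/GFP and LLC and by -1.14 between LLC/SeV/GM and LLC/SeV/GFP. The others differed by 0.13 to 0.47 and by -0.20 to -0.02. Spike-in scaling took the mean of all 8, so its shifts lean on that probe.

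The 29 gene lists were fixed before the data were examined, as were the named-gene rule, the size rule and the alternatives other than the added ones named here. They cover interferon, Toll-like receptor, antigen presentation, maturation and GM-CSF genes, markers of dendritic cell subsets and of other cells the preparation could hold, and housekeeping and metabolic genes. For each list and pair of arrays the median difference of members well above background on at least 1 array was set against 10000 random lists of the same size, matched in 20 bins of mean brightness. Counts of members at least 2-fold apart use the same members. The percentile is a description of these arrays. Of the 87 medians, 46 lay outside the central 95% of their random lists, where 4.35 would by chance if lists and genes were independent, which they are not.

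The genes named follow the fixed rule. They are (a) per direction the 12 genes furthest from both controls among those above background on all arrays, (b) per direction the 4 with the largest bound, (c) per direction the 8 furthest apart between LLC/SeV/GFP and LLC, (d) per direction the 8 furthest from LLC in both vector groups, (e) in each list up to 4 measured members with the largest difference, and (f) a fixed set of GM-CSF receptor, dendritic cell and interferon genes. Names that are only accessions, clone names or numbered predicted genes were counted but not named in (a) to (d). A gene named outside the rule is said to be so.

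The alternatives were normexp background correction with an offset of 50, median centring, quantile normalization, the 75th percentile over probes above background on all arrays, the deposited table, spike-in scaling, other filters on dim probes, a floor, the mean of all probes, limits of 1.5-fold and 3-fold, the mean of a pair of groups, unmatched random lists and the mean of list members. Cyclic loess scaling and a signal of at least 100 on the brighter side were added after the data were seen.

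The size rule was tested on simulated data for LLC/SeV/GM against both controls over 22658 genes with noise of the size between spots and every gene taken as above background. Of 50 genes changed by each fold it found 2% at 1.5-fold, 94% at 2.5-fold, 100% at 4-fold and 100% at 8-fold, and it called 0.0134% of 22458 unchanged genes. These shares hold for technical noise only, and each gene was given the median SD between spots of its brightness. For signals under 50 that median was 0.24, whereas the 90th percentile of the SD was 0.62. The noisiest dim probes were therefore not covered, and the share of unchanged genes called is too low for them. A further 100 simulations with no effect used normal noise of the size seen between the arrays, from the median absolute deviation in groups of brightness, so any true difference in the bulk of genes counts as noise and single large differences do not. These too took every gene as above background, so their counts lack the filter of the observed ones. The simulated counts of genes lower than both controls and of both vector groups against LLC were added after the data were seen. The number of arrays limits the precision of every value.

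Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, R 4.3.3 with limma 3.58.1 for normexp and cyclic loess, and matplotlib 3.10.9 for figures.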

Results

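Gene expression was measured in CD86-positive dendritic cells from the axillary lymph nodes that drain a tumour, in female C57/BL6N mice, 2 days after injection of tumour cells. The tumour cells were LLC, a Lewis lung carcinoma line of mouse origin. They were given unmodified (LLC), carrying a Sendai virus vector with the gene of green fluorescent protein (LLC/SeV/GFP), or carrying the vector with the gene of granulocyte-macrophage colony-stimulating factor, GM-CSF (LLC/SeV/GM), a cytokine that drives the growth and activation of dendritic cells and other myeloid cells. CD86 is a costimulatory molecule of activated antigen-presenting cells. Each of the 3 groups has 1 array, so no value has a replicate, no test was possible, and every difference describes a pair of arrays. Differences are given on the log2 scale, and a gene was counted when it differed by at least 2-fold and was well above background on the brighter side.

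Of 39429 probes, 62.6% were well above background on the LLC array, 68.4% on the LLC/SeV/GFP array and 66.2% on the LLC/SeV/GM array, and no spot was saturated. These probes gave 20017, 21923 and 21217 gene names above background, 22658 on at least 1 array and 19601 on all 3. Across the 19601 genes, which are not independent replicates, Pearson's r was 0.994 between LLC/SeV/GM and LLC, 0.991 between LLC/SeV/GM and LLC/SeV/GFP and 0.989 between LLC/SeV/GFP and LLC. The 399 probes printed 10 times on each array had a median SD between spots of 0.24 log2 units for signals under 50, 0.08 from 50 to 500 and 0.06 over 500. This is a technical spread and holds nothing of the spread between mice.

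The main comparison set LLC/SeV/GM against both controls, which asks what the GM-CSF gene adds to tumour cells that carry the vector. Genes induced by type I interferon were higher with LLC/SeV/GM. All 36 members of the list were higher than in each control, with a median difference of 0.91 from LLC/SeV/GFP and 0.93 from LLC, and 16 and 17 of them were at least 2-fold higher. Against both controls at once the median of the smaller difference was 0.85 and 14 members were at least 2-fold higher. Of 10000 random lists matched on brightness, 0 had as high a median in either comparison.

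Against both controls at once the largest difference within the list belonged to Ifit3, an interferon-induced antiviral protein, at 1.86 from LLC/SeV/GFP and 1.72 from LLC. Rsad2, the antiviral enzyme viperin, stood 1.55 and 1.60 higher, the dynamin-like GTPase gene Mx2 1.52 and 1.73 higher, and Oasl2, of the oligoadenylate synthetase family, 1.52 and 1.32 higher. Siglec1, a sialic acid receptor of macrophages, was 1.03 and 1.76 higher. Irf7, the transcription factor that amplifies interferon responses, had a signal of 1793 against 649.6 and 816.7, or 2.30-fold and 2.08-fold higher after scaling. The ubiquitin-like modifier Isg15, chosen after its values were seen, was 1.40 and 1.28 higher, and Ifit1, chosen in the same way, 1.29 and 1.54 higher. The probe of Ifit3 lies on chromosome 19 at 34663105 to 34663164, that of Rsad2 on chromosome 12 at 27127859 to 27127918, and that of Irf7 on chromosome 7 at 148450664 to 148451014 of the mouse build mm9.

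**Figure D1:**
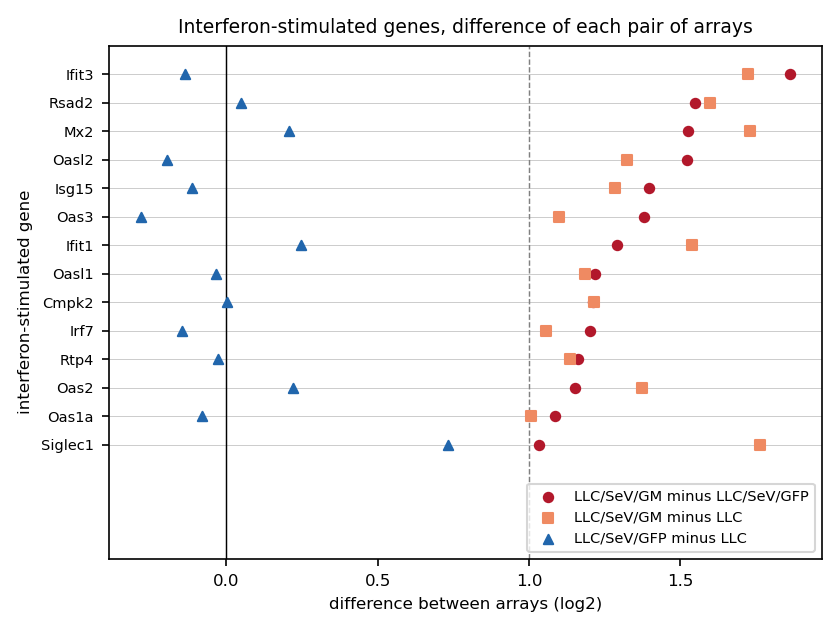
Difference in log2 units between each pair of arrays (horizontal axis) for the 14 interferon-stimulated genes at least 2-fold higher with LLC/SeV/GM than in both controls (vertical axis), 1 array per group; circles are LLC/SeV/GM minus LLC/SeV/GFP, squares LLC/SeV/GM minus LLC and triangles LLC/SeV/GFP minus LLC, and the dashed line marks 2-fold. All circles and squares lie beyond the dashed line because the genes were selected for this, and the other members of the list of 36 are not drawn. Those of Ifit3 lie at 1.86 and 1.72.

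The interferon genes themselves did not stand apart as a list. Of 12 type I and III interferon genes above background on at least 1 array, 11 were lower than in LLC/SeV/GFP, with a median of -0.24, and 6 were lower than in LLC, with a median of -0.01 that turned positive under another scaling. Both medians lay within the central 95% of matched random lists. The means were -0.69 and -0.12, and 1 of the 12 was at least 2-fold lower than both controls. Ifnb1, the interferon beta gene, was not well above background on any array. Ifna11 was -0.99 from LLC/SeV/GFP and -0.04 from LLC. The Ifna genes are near-identical, so values of single members are uncertain. Interferon gamma-induced genes had a median of 0.52 against LLC/SeV/GFP, with 14 of 18 higher, and 0.12 against LLC, which turned to -0.01 under another scaling. The chemokine gene Cxcl10 was 1.62 and 0.56 higher, and Fcgr1, a high-affinity IgG receptor, 1.29 and 1.56 higher. Cxcl9 differed by 0.85 from LLC/SeV/GFP and by -0.78 from LLC.

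Among single genes, Chil3, a chitinase-like protein of activated macrophages, had a signal of 4070 with LLC/SeV/GM against 776.5 with LLC/SeV/GFP and 893 with LLC, 4.37-fold and 4.32-fold higher. Fn1, fibronectin, was 3.71-fold and 5.10-fold higher, with a signal of 1783. Ifit3b was 4.05-fold and 3.43-fold higher, and a further probe of it was above background with LLC/SeV/GM only. The neutrophil protease gene Ctsg, cathepsin G, was 1.78 and 1.58 log2 units higher at a low signal of 77.1. The probe of Chil3 lies on chromosome 3 at 105950485 to 105950544 and that of Fn1 on chromosome 1 at 71632116 to 71632175 of mm9.

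Chil3, Fn1, Ifit3, Ifit3b and Ctsg are among the 12 genes furthest above both controls, and the remaining ones were dim in the controls, with signals under 100 there. Sntb1, a syntrophin, was 2.57 and 2.61 higher, but a dimmer probe of the same gene gave -0.075 and -0.17. Flg, filaggrin of the epidermis, was 3.07 and 2.56 higher, while its further probes were above background on no array. Ankrd6 was 2.29 and 2.55 higher, Slc13a3, a dicarboxylate transporter, 2.52 and 2.23, and Dnase1, a secreted deoxyribonuclease, 2.24 and 2.20. Cercam was 1.88 and 1.77 higher, and Slc5a10, a sodium-sugar cotransporter, 1.67 and 1.80. Genes above background with LLC/SeV/GM only were at least 31.6-fold higher for Rhbg, an ammonium transporter, at least 22.6-fold for the olfactory receptor gene Olfr1165, at least 14.7-fold for Prl7c1 and at least 13.8-fold for Bpifa1. These bounds use the lowest signal called above background as a floor, which need not be a detection limit. A defect of a single probe or spot cannot be told apart for such genes, and a further probe of Prl7c1 was above background on no array.

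**Figure D2:**
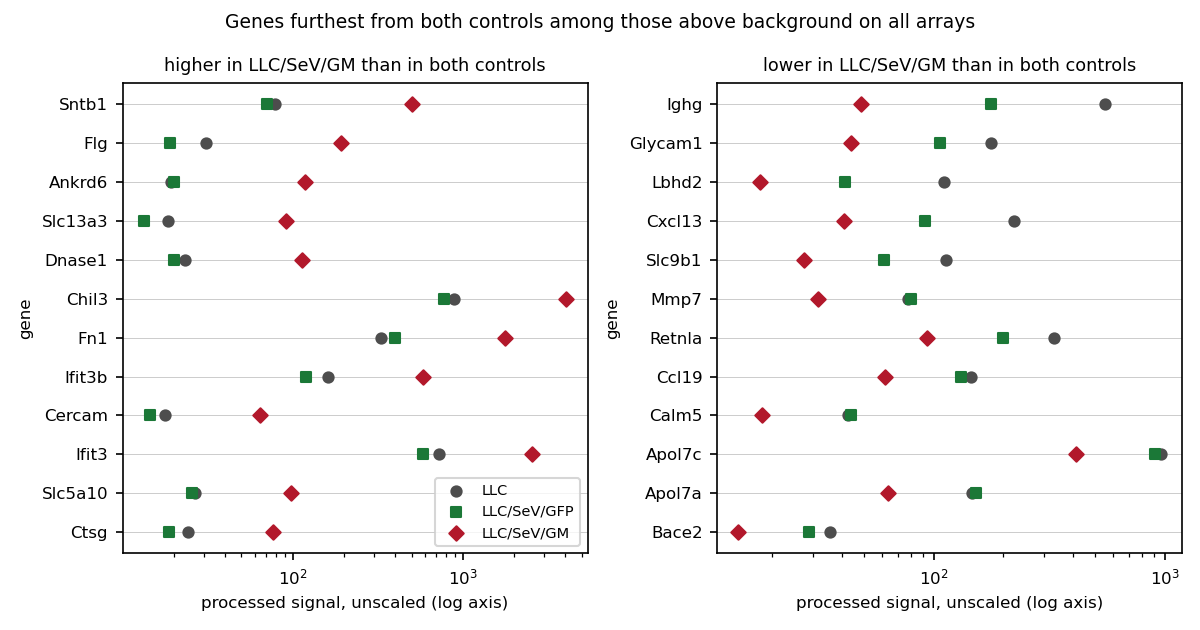
Processed signal on a log axis, before scaling between arrays, of the 12 genes furthest above (left panel) and the 12 furthest below (right panel) both controls among genes above background on all 3 arrays; each marker is 1 array. Chil3 has a signal of 4070 with LLC/SeV/GM and of 893 and 776.5 in the controls.

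Among genes lower with LLC/SeV/GM than in both controls, Cxcl13, which attracts B cells, differed by -1.43 from LLC/SeV/GFP and -2.53 from LLC. Glycam1, a mucin of high endothelial venules, differed by -1.54 and -2.09. Ccl19, a ligand of CCR7, differed by -1.36 and -1.32, while its dimmer probes gave -0.48 and -0.40 against LLC/SeV/GFP and -0.40 and -0.33 against LLC. The immunoglobulin gene Ighg, with many near-identical relatives, differed by -2.13 and -3.58. Retnla, a secreted product of alternatively activated macrophages, differed by -1.36 and -1.91, and the matrix metalloproteinase gene Mmp7 by -1.60 and -1.37. Apol7c had a signal of 412.2 against 908.9 and 963.4, a difference of -1.40 and -1.30, and Apol7a differed by -1.53 and -1.28. Lbhd2, Calm5 and Bace2 differed by -1.48, -1.54 and -1.28 from LLC/SeV/GFP and by -2.72, -1.31 and -1.40 from LLC. Slc9b1 differed by -1.42 and -2.13, but its other probe gave -0.13 and 0.62. Among genes whose brightest probe was not above background with LLC/SeV/GM, Speer9-ps1 was at least 7.84-fold lower and Prg2, the eosinophil major basic protein, at least 5.64-fold. Cdhr3 was at least 5.42-fold lower and Ppp1r1c at least 4.56-fold. However, a further probe of Ppp1r1c was above background on all 3 arrays and gave -0.07 and -0.21, so its bound holds for 1 probe only.

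Csf2, the gene of GM-CSF, had a low signal on all 3 arrays, 48.6 with LLC/SeV/GM, 34.7 with LLC/SeV/GFP and 37.1 with LLC, differences of 0.22 and 0.31. Its receptor chains were higher by 0.21 and 0.28 for Csf2ra and by 0.06 and 0.35 for Csf2rb. Csf2rb2 differed by -0.16 and 0.22, and by 0.105 and 0.25 on its other probe. The list of GM-CSF receptor and STAT5 target genes had a median of 0.21 against LLC/SeV/GFP, with 13 of 17 higher, and of 0.12 against LLC, with 11 higher, the latter turning just negative under another scaling. Pim1 was 0.55 and 0.22 higher, Il2ra 0.44 and 0.58 higher, and Cish, a feedback inhibitor of STAT5, 0.39 and 0.43 higher. None of the 17 reached 2-fold.

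Markers of dendritic cell activation had no common direction. Of 27 maturation genes 15 were higher than in LLC/SeV/GFP and 12 higher than in LLC, and 0 reached 2-fold. The genes with values here are of the fixed set. Il12b and Ccl5 were among the list members furthest apart in both comparisons, and their values and directions are not given here. Cd86, the molecule the cells were selected on, was 0.45 higher than in LLC/SeV/GFP and 0.34 higher than in LLC. The dendritic cell integrin gene Itgax was 0.38 and 0.16 higher. Cd83 differed by 0.11 and -0.27, Cd40 by -0.17 and -0.18, and the migration receptor gene Ccr7 by -0.06 and -0.25. Cd80 differed by -0.29 and 0.30 on its brighter probe and by 0.55 and 0.12 on the other. The maturation list of 27 genes had medians of 0.02, with a mean of -0.01, and -0.06, both inside the central 95% of random lists, and the former turned to -0.02 under another scaling.

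All 14 genes of MHC class II presentation were higher than in LLC/SeV/GFP, with a median of 0.33 and at least 13 higher under every scaling tried. Against LLC 7 were higher and 7 lower, the median was 0.00 and the mean 0.02, and the median took either sign over the scalings. H2-DMb2 was 0.77 above LLC/SeV/GFP and 0.10 above LLC, and Ciita, the master regulator of these genes, 0.41 and 0.45 higher. B cell markers leaned the same way against LLC/SeV/GFP, with a median of 0.38 and 14 of 15 higher. Whether the class II difference came from dendritic cells or from a different share of B cells was not tested. MHC class I genes had medians of 0.06 and -0.09, inside the central 95%, the latter turning just positive under another scaling.

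The Toll-like receptor list had medians of 0.14 and 0.07, the latter turning to -0.05 under another scaling. Tlr7, a sensor of single-stranded RNA, was 0.62 and 0.34 higher and its other probe 0.65 and 0.59 higher, whereas Tlr9, a sensor of DNA, differed by -0.05 and -0.13. Cd14, which binds bacterial lipopolysaccharide, was 1.42 and 0.38 higher. Inflammatory cytokine and chemokine genes had medians of 0.27 and -0.03, the latter turning just positive under another scaling. Of 24 members 9 were lower than in LLC/SeV/GFP and 13 lower than in LLC. Among the higher ones, Il6 was 1.06 and 0.36 higher and Ccl2 1.08 and 0.35 higher. Inhibitory and regulatory molecules had medians of 0.19 and 0.10, the latter turning to -0.03 under another scaling. Of 14 members 5 were lower than in LLC/SeV/GFP, 1 of them at least 2-fold, and 6 lower than in LLC. Among the higher ones, Lilrb4a was 1.08 and 0.52 higher and Cd274, the ligand of the checkpoint receptor PD-1, 0.92 and 0.39 higher.

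Plasmacytoid dendritic cell markers were lower, with 11 of 16 below LLC/SeV/GFP at a median of -0.37 and 12 of 16 below LLC at a median of -0.18. Siglech, a receptor of these cells, differed by -0.35 and 0.05, and its other probe by -1.102 and -0.437. Cox6a2 differed by -1.17 and -0.58, Upb1 by -0.70 and -0.54, and Bst2, which interferon also induces, by 0.36 and 0.50.

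Markers of other cells differed beside these genes. Monocyte and macrophage markers had medians of 0.31 and 0.32 against the controls, with 10 and 15 of 18 higher, and 0 of 10000 random lists had as high a median. Lysozyme, Lyz2, was 1.08 and 0.60 higher, and the macrophage marker gene Adgre1 0.78 and 0.50 higher, whereas Marco differed by -0.86 and 0.24 and C1qc by -0.56 and 0.18. B cell markers had medians of 0.38 and 0.13, with 14 and 11 of 15 higher, both outside the central 95% of random lists. T cell markers had medians of -0.11 and -0.17, the former turning to 0.12 under another scaling, with Cd3e at -0.11 and -0.41. Natural killer cell markers had medians of 0.00, which took either sign over the scalings, and -0.10. Cross-presenting dendritic cell (cDC1) markers had medians of 0.05 and 0.11 and cDC2 markers of -0.07 and -0.01, all within the central 95% and all turning sign under another scaling, and the cDC2 mean against LLC was 0.03. Of the cDC1 markers 7 and 10 of 14 were higher, and of the cDC2 markers 5 and 6 of 12. In these lists Naaa was 0.98 and 0.92 higher and Ear2 1.11 and 1.38 higher, whereas a dimmer probe of Cd209a gave -1.088 and -0.805. Skin-derived dendritic cell markers had medians of -0.08 and -0.13, of which the former turned to 0.15 under another scaling and the latter had a mean of 0.08. Of these 8 markers 4 and 5 were lower, 1 of them at least 2-fold against LLC/SeV/GFP, while Cd207, langerin, was 1.26 and 1.54 higher. Neutrophil markers had medians of -0.17, which turned to 0.06 under another scaling, and -0.12, with Mpo, myeloperoxidase, 1.25 and 1.11 higher, while a dimmer probe of Mpo, above background with LLC/SeV/GM only, does not settle the difference from LLC.

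In all, 327 genes were at least 2-fold higher with LLC/SeV/GM than in both controls and 73 were lower. Against LLC/SeV/GFP alone 455 were higher and 1339 lower, and against LLC alone, which leaves out the array that stood apart most, 706 were higher and 363 lower. The share of higher genes depended on the scaling, at 25.4% against LLC/SeV/GFP but 40.0% with median centring, 37.7% with quantile normalization and 44.3% with spike-in scaling, and at 66.0% against LLC but 42.0% with normexp background correction. Among genes above background on all 3 arrays 75 were higher and 42 lower than both controls, and with normexp background correction 41 and 9, all of which were among the 327 and 73. Independent lists would share 14.2 higher and 21.4 lower genes, but the comparisons share the LLC/SeV/GM array and are not independent. These 2 values are therefore no reference for the observed overlap. Lists that share an array also overlapped widely in simulations with no effect. In 100 simulations with no effect and noise of the size seen between arrays, a median of 163.5 genes were higher than both controls, from 129 to 191, with medians of 468.5 against LLC/SeV/GFP alone and 466 against LLC alone. A median of 168.5 genes were lower than both controls in them. The simulations took every gene as above background, whereas the observed 327 and 73 had to be above background on the brighter side. The simulated counts are therefore not like the observed ones, and no excess or lack is read from setting them side by side.

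**Figure D3:**
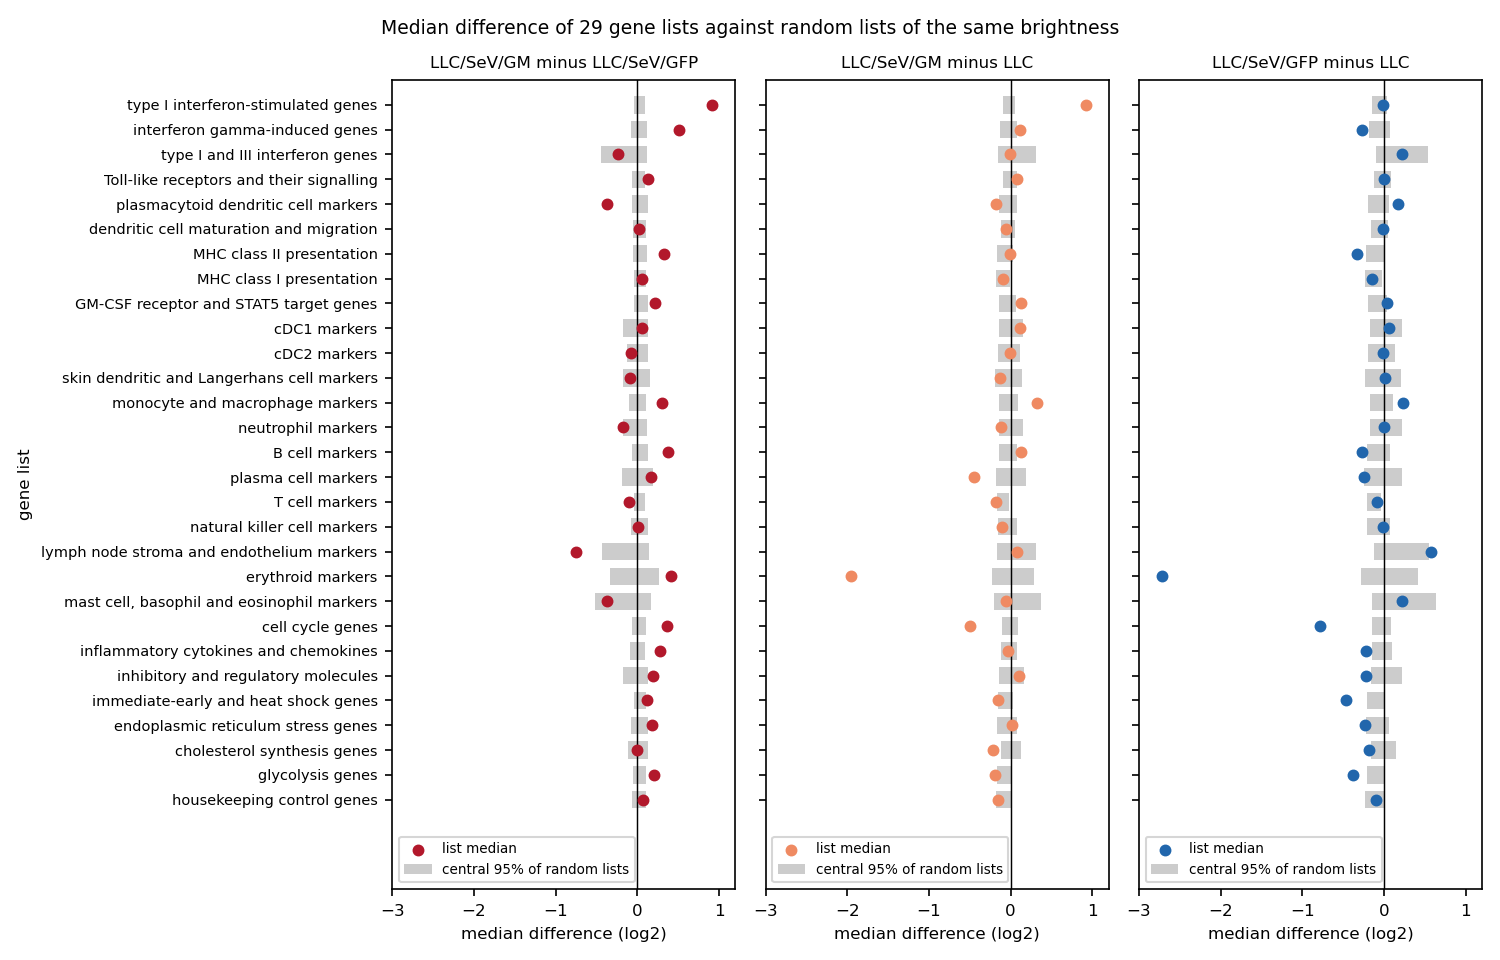
Median log2 difference (horizontal axis, points) of the 29 gene lists (vertical axis) in each pair of arrays, with the central 95% of the medians of 10000 random lists of the same size and brightness (grey bars). The interferon-stimulated genes lie at 0.91 and 0.93 in the panels of LLC/SeV/GM and at -0.01 in the panel of LLC/SeV/GFP minus LLC.

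The comparison of LLC/SeV/GFP with LLC asks what the vector does without the GM-CSF gene. Interferon-stimulated genes did not stand apart, with 17 of 36 higher, a median of -0.01, a mean of 0.03 and 0 at least 2-fold apart, and the median ran from -0.37 to 0.05 over the scalings. Cell cycle genes were lower with LLC/SeV/GFP, with a median of -0.78, 22 of 24 lower and 9 at least 2-fold lower, and no scaling brought the median above -0.70. Haemoglobin genes were lower by more, with Hbb-bt at -2.96, Hbb-b2 at -2.94, Hba-a2 at -2.77 and Hba-a1 at -2.71. The haemoglobin genes are near-identical within each pair, so their values are not separate measurements. Hbb-bt and Hba-a1 are among the erythroid markers, and a different share of such cells between the arrays was not told apart from an effect of the vector.

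Within the cell cycle list, Birc5, survivin, differed by -1.29, and its other probes by -1.27 and -1.13. The mitotic kinase genes Bub1 and Plk1 differed by -1.16 and -1.13, the cyclin gene Ccnb2 by -1.15, and Mki67, the antigen of proliferating cells, by -0.84. Cdk1 differed by -1.13 on its brightest probe and by 0.15 on a dimmer one. LLC/SeV/GM lay between the other arrays, 0.36 above LLC/SeV/GFP and -0.50 from LLC in the median of the list. Of the 5 erythroid markers above background, 3 were at least 2-fold lower than in LLC, and the median was -2.71, from -3.07 to -1.02 over the scalings. With LLC/SeV/GM it was -1.96 from LLC, from -2.08 to -1.09, and 0.41 from LLC/SeV/GFP, from 0.07 to 0.65. Alas2, the enzyme that starts haem synthesis in red cell precursors, differed by -2.89.

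Several lists of immune genes were lower with LLC/SeV/GFP as well. Interferon gamma-induced genes had a median of -0.27, with Cxcl9 at -1.63 and Cxcl10 at -1.05, and MHC class II genes of -0.33, with 13 of 14 lower. B cell markers had a median of -0.27, with 13 of 15 lower, and inflammatory cytokine and chemokine genes of -0.22, with 13 of 24 lower. Inhibitory and regulatory molecules had a median of -0.22, with 11 of 14 lower and Cd274 at -0.53. All of these kept their sign under the scalings tried. Monocyte and macrophage markers had a median of 0.24 and plasmacytoid markers of 0.17, and both turned negative under another scaling.

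The gene furthest apart was Klra4, a lectin-like receptor gene, with a signal of 74.9 with LLC/SeV/GFP against 2691 with LLC and 3069 with LLC/SeV/GM, a difference of -4.98 from LLC. Its only probe lies on chromosome 6 at 129994035 to 129994094 of mm9. The 17 other members of the Klra family above background differed by -0.64 to 0.77, with a median of 0.12, and the natural killer cell list by -0.01. Lgals7, a galectin of stratified epithelia, differed by -3.28 and Boc by -2.22. The genes furthest above LLC were all dim, with LLC signals under 50. Mrgprf was 3.15 higher, Ypel2 2.61, Adh5 2.59, Magi1 2.46, Atp13a4 2.45, the Wnt inhibitor gene Wif1 2.42, Pcdhb21 2.37 and Pabpc2 2.36. Magi1 had a further probe above background, which gave 0.08.

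The counts were 1885 genes higher and 408 lower with LLC/SeV/GFP than with LLC, a share of 82.2% higher. That share depended on the scaling, at 69.6% with median centring, 69.9% with quantile normalization, 63.4% with normexp background correction and 58.1% with spike-in scaling. The array of LLC/SeV/GFP was higher than both others for 1007 genes and lower for 39, and dim genes leaned towards it, with a median difference from LLC of 0.165 in the dimmest of 10 groups, 0.22 in the next and -0.16 in the brightest.

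**Figure D4:**
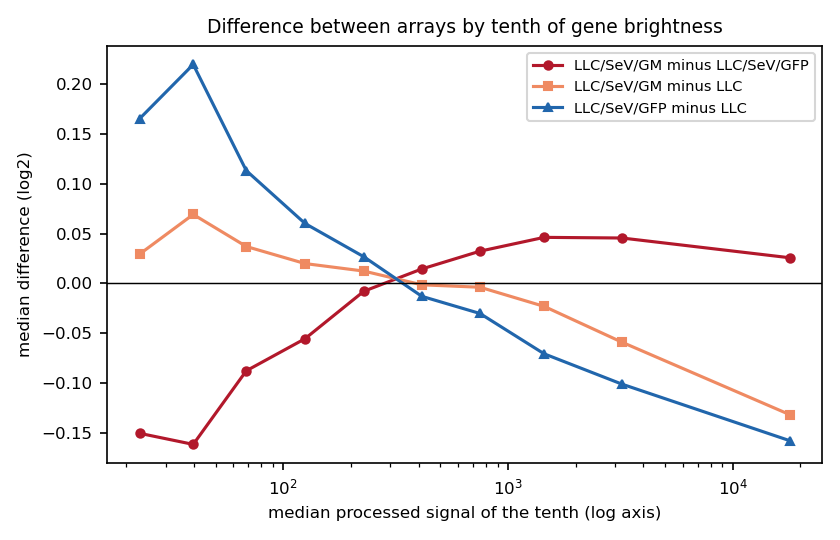
Median log2 difference between each pair of arrays (vertical axis) in 10 groups of the 19601 genes above background on all arrays, ordered by brightness (horizontal axis, median processed signal, log axis). LLC/SeV/GFP minus LLC is 0.22 at a signal of 39.8 and -0.16 in the brightest group.

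The last comparison took the genes on which both Sendai virus groups stood on the same side of LLC. Among genes above background on all 3 arrays, Alas2 at -2.89 with LLC/SeV/GFP and -2.48 with LLC/SeV/GM and the haemoglobin gene Hbb-b2 at -2.94 and -2.29 were furthest below LLC. Hba-a2 stood at -2.77 and -2.06, Hba-a1 at -2.71 and -1.96, and Hbb-bt at -2.96 and -1.96. Jchain, the joining chain of secreted antibodies, stood at -1.98 and -2.81. Jchain is among the plasma cell markers, and Alas2, Hba-a1 and Hbb-bt are among the erythroid markers. Whether the share of such cells differed between the arrays was not tested. Tgfbrap1, a factor that binds TGF-beta receptors, stood at -2.05 and -2.10. Cpd stood at -2.19 and -2.33, but its other probe was above background with LLC/SeV/GFP only.

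Genes higher in both vector groups were mostly dim. The brightest of those named was Cbr2, a carbonyl reductase, 1.08 and 1.13 higher and 0.94 and 1.08 higher on its other probe. Tbx3, a T-box transcription factor, was 1.66 and 1.34 higher, and Krt75, a hair follicle keratin, 1.63 and 1.35 higher. Tcerg1l was 1.94 and 1.18 higher, Tfcp2l1 1.90 and 1.27, Pramel39 1.44 and 1.11, Ccdc177 1.41 and 1.16, and Cyp2d10 was 2.14-fold and 2.20-fold higher. In total 240 genes were higher in both and 255 lower. Independent lists would share 58.7 and 6.54, but both comparisons use the same LLC array and so are not independent. Simulations with no effect gave medians of 162 and 164, without the filter on dim genes that the observed counts had. With a signal of at least 100 on the brighter side, 3 genes were higher and 75 lower. The share of higher genes was 48.5%, and 33.3% with quantile normalization, 32.9% with the authors' deposited table, 32.9% with spike-in scaling and 1.59% with normexp background correction.

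The count of genes on which 1 array stood apart from both others was set side by side for all 3 arrays. It was 255 higher and 240 lower for LLC, 1007 and 39 for LLC/SeV/GFP, and 327 and 73 for LLC/SeV/GM. With normexp background correction it was 62 and 1, 86 and 4, and 41 and 9 in the same order.

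**Figure D5:**
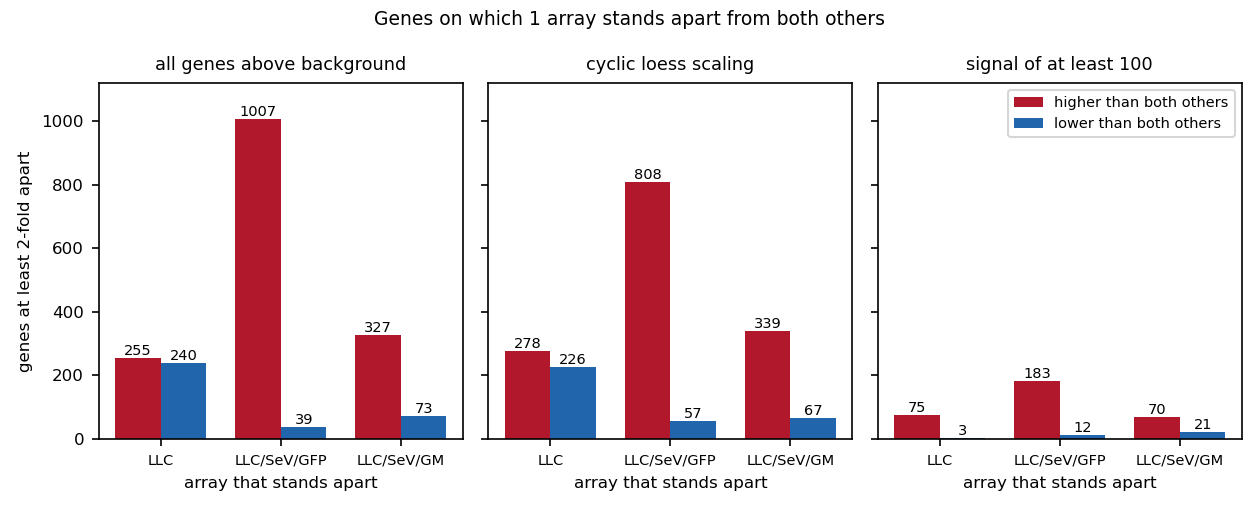
Number of genes (vertical axis) at least 2-fold higher (red) or lower (blue) on 1 array (horizontal axis) than on both others, for all genes above background, with cyclic loess scaling, and with a signal of at least 100 on the brighter side. LLC/SeV/GFP has 1007 higher genes in the left panel, 808 in the middle and 183 on the right.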

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

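Of the tests in this part, cyclic loess and the signal of at least 100 were chosen only after the result was seen. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out in turn within a group. Beside the number of arrays, signal over background limits these results, since the genes called higher than both controls had a median signal of 36.6 with LLC/SeV/GM, and spots under 50 had a median SD of 0.24. Of the counts under the alternatives 76 stayed within 1.5 times the main count and 68 did not. Median centring, the floor, the 75th percentile over probes above background, cyclic loess and the mean of all probes moved no count beyond that. Of the list shifts 1008 moved by less than 1 SD of matched random lists and 123 by more, and no shift of a list outside the central 95% changed sign, although some list medians did as a scaling moved all genes. Of values of single genes 1822 stayed within the SD between spots of a difference and 1090 moved further. A value was read as reversed only if it was at least 2-fold in the main setting, and 4 were.

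Counts are given as higher and lower for LLC/SeV/GM against LLC/SeV/GFP, LLC/SeV/GM against LLC, LLC/SeV/GFP against LLC, LLC/SeV/GM against both controls, and both vector groups against LLC, in that order. With normexp background correction they were 72 and 134, 63 and 87, 161 and 93, 41 and 9, and 1 and 62. This setting changed the background correction and added an offset to every signal, which shrinks the differences of dim genes, and these were not tried apart. Genes above background on every array compared gave 169 and 684, 146 and 135, 745 and 207, 75 and 42, and 27 and 70, since fewer genes can pass. With no filter on dim probes they were 931 and 2316, 1407 and 895, 2864 and 854, 529 and 285, and 648 and 502, since more can. A limit of 1.5-fold gave 1064 and 2859, 1675 and 851, 3571 and 980, 610 and 235, and 825 and 512. A limit of 3-fold gave 254 and 461, 360 and 218, 870 and 211, 205 and 20, and 77 and 163. With a signal of at least 100 on the brighter side they were 117 and 251, 87 and 101, 314 and 160, 70 and 21, and 3 and 75.

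Spike-in scaling, which shifts every gene of an array alike, gave 858 genes lower in LLC/SeV/GM than in LLC/SeV/GFP, 1147 higher and 826 lower in LLC/SeV/GFP than in LLC, and 157 higher in both vector groups. Genes higher in both vector groups numbered 143 with quantile normalization and 140 with the deposited table, and the cause was not tested. With the mean of a pair of groups in place of each, 164 genes were lower in LLC/SeV/GM than in the controls and 642 higher in the vector groups, since 1 array of the pair can then carry a gene.

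The shift of the interferon-stimulated genes from their random lists kept its direction against both controls. LLC/SeV/GM minus LLC/SeV/GFP gave 0.79 with normexp, 0.83 with the mean of all probes, 0.93 with unmatched random lists and 0.92 with the mean of the members. LLC/SeV/GM minus LLC gave 0.88 with normexp and 1.03 with the mean of all probes. LLC/SeV/GFP minus LLC gave -0.03 with unmatched lists. The cause was not tested for these. The share of higher genes in LLC/SeV/GM against LLC/SeV/GFP was 25.4%, but 40.0% with median centring, 37.7% with quantile normalization, 37.6% with the deposited table and 44.3% with spike-in scaling. Against LLC it was 66.0% and 42.0% with normexp, and for LLC/SeV/GFP against LLC 82.2%, 63.4% with normexp and 70.0% with the deposited table. Against both controls it ran from 81.4% to 85.9%.

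The 4 reversals came from another probe of the same gene that was above background on at least 1 array of the pair, and smaller differences that changed sign are not counted. Cpd in LLC/SeV/GFP minus LLC was 3.12, taken against an LLC value not above background, Slc9b1 in LLC/SeV/GM minus LLC 0.62, and Sntb1 -0.075 in LLC/SeV/GM minus LLC/SeV/GFP and -0.17 in LLC/SeV/GM minus LLC, and the cause was not tested. Of the 327 genes higher than both controls, 320 were called again with cyclic loess, 318 with median centring, 309 with quantile normalization and 304 with spike-in scaling.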

Other observations

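The tests of the vector, of plasmacytoid cells and of monocytes in this part were chosen only after the result was seen. The rule that tests on other probes decide nothing where fewer than 20% of the genes have such a probe was also set after the values were seen, because medians over 66 of 1007 and 15 of 876 genes say little of the rest, and it turned 2 tests into undecided ones.

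Lymph node stroma and endothelium markers were lower with LLC/SeV/GM than with LLC/SeV/GFP, with a median of -0.75 and 9 of 12 lower, and showed no lean against LLC, where the median of 0.07 took either sign over the scalings. Ccl21a, a ligand of CCR7 made by stromal cells, differed by -1.33 and -1.01, the collagen gene Col1a2 by -1.16 and 0.09, and Dcn, decorin, by -1.21 and -0.53. LLC/SeV/GFP stood 0.58 above LLC on the same list. Plasma cell markers had a median of -0.44 between LLC/SeV/GM and LLC and of -0.25 between LLC/SeV/GFP and LLC, and of 0.17, with a mean of -0.02, between the vector groups. Derl3, of the machinery that removes misfolded secreted proteins, differed by -0.94 and -1.08 from LLC. Mast cell, basophil and eosinophil markers had medians of -0.37 and -0.06, within the central 95% of random lists, with Cpa3, a mast cell protease gene, at -1.05 and -1.08 and the basophil protease gene Mcpt8 at 1.41 and 0.40.

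Metabolic and stress genes were lower in LLC/SeV/GFP than in LLC under every scaling tried. Glycolysis genes had a median of -0.38, with 14 of 16 lower and Tpi1 at -0.66, and immediate-early and heat shock genes of -0.47, with 17 of 18 lower and Jun at -0.88. Endoplasmic reticulum stress genes had a median of -0.23 and cholesterol synthesis genes of -0.18. Housekeeping genes had a median of -0.10 that turned to 0.03 under another scaling and lay within the central 95%. LLC/SeV/GM minus LLC/SeV/GFP gave 0.21 for glycolysis, 0.12 for immediate-early, 0.18 for endoplasmic reticulum stress, 0.00 for cholesterol synthesis and 0.06 for housekeeping genes. LLC/SeV/GM minus LLC gave -0.19, -0.16, 0.02, -0.22 and -0.16 in the same order. The medians of cholesterol synthesis in the former and of endoplasmic reticulum stress in the latter took either sign over the scalings.

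Interferon-stimulated genes were higher with LLC/SeV/GM than in both controls by a median of 0.85, and all 36 members were higher under each of 9 scalings. A scaling or brightness trend is argued against by the lowest median over those scalings, 0.736 with normexp background correction. With the vector and GFP alone the median was -0.008 from LLC, so no rise was seen on that array. That value largely restates the higher level against both controls and is not separate evidence about the vector. A larger share of plasmacytoid dendritic cells is argued against by the 15 markers outside the list, with a median of the smaller difference of -0.171. This holds only as far as the RNA of these markers follows the share of the cells. A larger share of monocytes or macrophages cannot be told apart from an effect of the GM-CSF gene. Of 9 markers picked by hand as abundant, 2 were at least 0.3 higher than in both controls and 6 were not higher than both. The 2 were Lyz2 at 0.60 and Csf1r, chosen after its values were seen, at 0.36. Adgre1, Cd14 and Fcgr1, left out of the 9, were also at least 0.3 higher than in both controls. Of the full list of 18 markers 9 were higher and 2 lower than both controls, with a median smaller difference of 0.11. Of 10000 random lists 0 had as high a median. Selection on CD86 does not remove such cells. An effect of the GM-CSF gene stays a possible explanation, with 1 array per group and no replicate to set it against.

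The LLC/SeV/GFP array was higher than both others for 1007 genes. A brightness trend of that array may account for part of this and not for the whole, as 808 such genes were counted after cyclic loess, which removes the trend, and 705 after quantile normalization. With normexp background correction only 86 were, where LLC had 62 and LLC/SeV/GM 41, so the size of the excess depends on how dim signals are corrected. A change of the genes themselves cannot be told apart from other defects of the array, because only 66 of the 1007 genes had another probe above background. Those 77 probes had a median difference of 0.909 from the mean of the other arrays, where 112 other probes of dim genes outside the pattern had 0.19.

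Of the genes at least 2-fold higher on 1 array than on both others, 876 were not above background on either of the others, 162 on LLC, 486 on LLC/SeV/GFP and 228 on LLC/SeV/GM. Uneven spots are argued against for these genes as a set, since their median ratio of pixel SD to mean was 1.107 times that of spots of the same brightness. Removing flagged spots beforehand left out only 2 probes, and a median does not exclude uneven spots for some of the genes. A defect of single probes cannot be told apart, with only 15 of the 876 genes covered by 16 other probes, whose median difference was 1.298. Nor can a defect of single spots. Probes printed 10 times held 9 such genes where 18.1 were expected among 283 genes. That ratio of 0.497 is close to the 0.5 set beforehand and rests on few genes. A probe also counted as above background if any of its spots did. Probes printed 10 times therefore enter or miss this pattern on other terms than single spots, with or without a defect. No biological explanation was tested for these genes.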
